A study of Homo sapiens with 32 samples.

How the data were processed

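RNA levels were measured in 32 samples of 2 human lung cancer lines, A549 and H460a, given vehicle or 2 µM RO4929097 for 6 or 24 h, with 4 replicates in each of the 8 groups. Per the labels, cells were plated at 35% confluency, rested overnight before dosing and lysed in Buffer RLT, and RNA was prepared with RNeasy Mini columns. A total of 15 µg RNA entered cDNA synthesis with poly-A RNA controls, and cRNA was labelled with biotin. The deposited values are an intensity for each of 54675 probe sets of an Affymetrix array, made by the authors with RMA per the submitters' processing notes. The RMA version, its software and the image files are not given in the sources used here. The values are on a linear scale, judged from the values themselves, and were log2-transformed here without further scaling. A note in the sample descriptions on embryos has no counterpart in the other labels and was not used here.

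The 62 control probe sets were left out, as were, for gene tests, 1801 probe sets with several gene symbols and 11721 with no gene named. The 41091 probe sets with 1 symbol stand for 19775 genes. For the 10523 genes with more than 1 probe set, the probe set with the highest mean over the 32 arrays was used. Gene ids of 41043 of these probe sets were found in the reference table, and 0 symbols were updated.

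Means of the 8 groups were fitted with limma 3.58.1 (lmFit and eBayes with default settings) in R 4.3.3 over all 32 arrays, with a total of 31.89 degrees of freedom, of which 7.888 from the prior. The contrasts were GSI against vehicle in each line at each time, their average, the differences of this effect between lines and between times, 24 h against 6 h in vehicle, and A549 against H460a in vehicle. P-values were adjusted by the Benjamini-Hochberg method over genes within each contrast, and adjusted p under 0.05 is the threshold. The model, the named genes, the gene lists and most of the alternatives were chosen before the data were examined. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3.

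Genes were named by rule. For each GSI comparison these are up to 10 genes with the largest rise and 10 with the largest fall among those past the threshold whose 4 GSI arrays lie on the same side of the 4 vehicle arrays. Always included are the members of the gamma-secretase complex and HES1, HES4, HEY1, HEYL, NRARP, NOTCH3, MYC, CCND1, JAG1, IL6 and CXCL8. Up to 4 members of each other list past the threshold are added. The averaged effect and the differences of effects name up to 5 genes in each direction, and the time and line comparisons up to 8 with arrays that do not overlap. SAT1, ADAM19 and BCL6 were named after their values were seen, as the other Notch targets past the threshold in A549 at 24 h.

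The 29 gene lists, written from general knowledge, hold 758 genes, 692 of them measured. They are: Notch pathway targets, Notch receptors ligands and cofactors, gamma-secretase complex, gamma-secretase substrates, inflammatory cytokines and chemokines, collagens and extracellular matrix, epithelial-mesenchymal transition, S phase, G2 and mitosis, p53 targets, hypoxia and glycolysis, NRF2 targets, unfolded protein and amino acid stress, cholesterol synthesis, type I interferon response, TGF-beta response, YAP and TEAD targets, immediate early genes, aryl hydrocarbon and drug metabolism, alveolar type II cell markers, goblet and club cell markers, neuroendocrine markers, ciliated cell markers, basal cell and keratin markers, fibroblast markers, leukocyte and endothelial markers, ribosomal proteins, oxidative phosphorylation, and glucocorticoid and cAMP response. Each was compared with all other genes by limma camera with a preset inter-gene correlation of 0.01, adjusted over the 29 lists, and again with an estimated correlation. The list tests were planned for the 4 GSI comparisons, and those for the other contrasts were added later.

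Alternatives were fitting the comparison's own arrays or each line alone, leaving out genes under the median level, other ways to handle several probe sets, centring, quantile normalization over all arrays or within each line, eBayes with trend and robust, array weights, a block for the replicate number, a difference of at least 0.58, and leaving out each array in turn. Leaving out 4 arrays that stand apart, and technical covariates were chosen after seeing the data, as were the tables that set list and gene directions beside each scaling.

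The steps were tested on simulated data with independent genes of the same number, where 50 genes each were changed by 1.25, 1.5, 2 and 4 fold. In A549 at 6 h 27, 49, 50 and 50 were found (13 of 189 calls false). In A549 at 24 h 26, 49, 48 and 50 were found (10 of 183 calls false). In H460a at 6 h 24, 42, 50 and 50 were found (2 of 168 calls false). In H460a at 24 h 19, 48, 50 and 50 were found (10 of 177 calls false). In the difference between lines at 24 h 6, 31, 50 and 50 were found (10 of 147 calls false). A list shifted downward was found lower in all 5 comparisons, and of the other lists 1, 0, 0, 0 and 2 passed.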

Results

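The arrays measured transcript levels in the human lung cancer lines A549, derived from an adenocarcinoma and H460a, derived from a large cell carcinoma. H460a is the name in the sample labels, and the series text calls the line H460. Cells were given vehicle or 2 µM of RO4929097, an inhibitor of gamma-secretase (GSI), for 6 or 24 h. Gamma-secretase is the protease complex that cleaves activated Notch receptors and other membrane proteins inside the membrane, and the series title calls the compound a Notch inhibitor. There were 4 arrays in each of the 8 groups, 32 in all, and 19775 genes were tested. The number of arrays limits the precision: the median standard error of a difference between 2 groups of 4 was 0.087 on the log2 scale. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these arrays, which may be technical. Differences are log2 values, GSI minus vehicle unless stated, ± the standard error from limma, with n = 4 arrays per group, and group levels are log2 intensities as mean ± SD.

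The arrays differed in mean intensity. The 4 A549 vehicle arrays at 6 h lay between 468 and 496, and A549 GSI arrays 1 and 2 at 6 h at 496 and 531. A549 GSI arrays 3 and 4 at 6 h lay at 589 and 583, and the other 24 arrays between 570 and 613. In H460a vehicle array 3 at 6 h the 3' probe set of beta-actin exceeded the 5' probe set by 2.19 on the log2 scale, against 0.14 to 0.42 in the other 31 arrays.

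**Figure D1:**
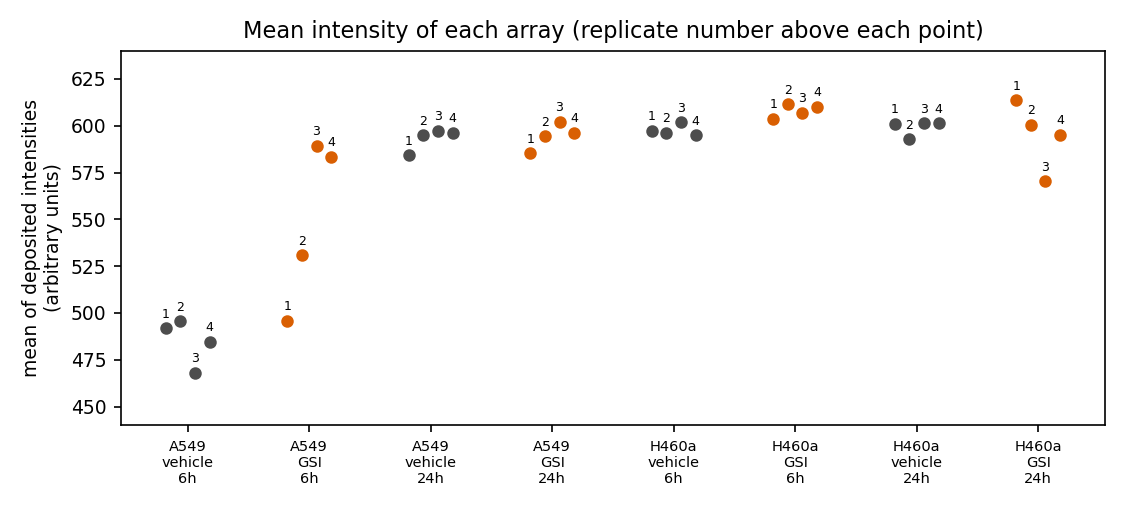
Mean of the deposited intensities of each of the 32 arrays (vertical axis, arbitrary units, not starting at 0) by group, with grey points for vehicle, orange points for GSI and the replicate number above each point. The 4 A549 vehicle arrays at 6 h lie between 468 and 496, and A549 GSI arrays 3 and 4 at 6 h lie at 589 and 583.

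GSI and vehicle were compared in A549 at 24 h to show which transcripts had changed after a day of exposure. HES1, a transcriptional repressor and a target gene of Notch, fell by 2.18 ± 0.13, from 9.98 ± 0.12 in vehicle to 7.80 ± 0.14 with GSI (adjusted p = 1.29e-13). PMEPA1, an inhibitor of SMAD signalling that TGF-beta induces, fell by 1.74 ± 0.074 (adjusted p = 2.19e-17), and TNFAIP6, a secreted hyaluronan-binding protein, fell by 1.72 ± 0.11 (adjusted p = 3.17e-13). TM4SF20, a membrane protein of the tetraspan type, rose by 1.48 ± 0.10 (adjusted p = 6.18e-12). BPIFA1, a secreted protein of the airway surface, rose by 1.38 ± 0.10 and RBP4, the plasma carrier of retinol, by 1.27 ± 0.14.

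In all 437 genes passed the threshold, 262 higher and 175 lower. Besides HES1, PMEPA1 and TNFAIP6, the largest falls were those of C3orf80 (-1.55), SPOCK1 (-1.06), RNF182 (-0.99), NPTX1 (-0.95), TYRP1 (-0.93), SNAI2 (-0.91) and VGLL3 (-0.88). With GSI C3orf80 lay at 5.03 and TYRP1 at 4.69, near the background, so the sizes of these 2 falls are lower limits. SNAI2 encodes Slug, a repressor of E-cadherin, and SPOCK1 a proteoglycan of the extracellular matrix. After TM4SF20, BPIFA1 and RBP4 the largest rises were those of FCGBP (0.98), a protein of mucus, and CIDEC (0.90), a protein of lipid droplets. ATP8B4 rose by 0.78, RAB37 by 0.78, the bradykinin receptor gene BDKRB2 by 0.76, PPL by 0.72 and SLC51B by 0.71.

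Among the Notch pathway targets, 1 of 31 members rose and 6 fell (3 and 6 adjusted over the list alone). Next to HES1 and SNAI2 these were HEY1 (-0.62), HES4 (-0.50), SAT1 (-0.47), ADAM19 (-0.36) and, higher, BCL6 (0.28). The list was lower than other genes (adjusted p = 0.00763, and adjusted p = 0.0657 with an estimated correlation), although its median was -0.0074. NRARP differed by 0.19 ± 0.067, HEYL by 0.10 ± 0.11, NOTCH3 by 0.038 ± 0.079, MYC by -0.10 ± 0.063, CCND1 by 0.053 ± 0.079 and JAG1 by -0.18 ± 0.10, none past the threshold. Of the 5 genes of the gamma-secretase complex none passed (1 higher adjusted over the list alone), with APH1A at -0.014, APH1B at 0.22, NCSTN at 0.12, PSEN2 at 0.081 and PSENEN at -0.11.

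Of the TGF-beta response genes, 12 of 27 (14 adjusted over the list alone) fell and none rose, with a list median of -0.27 (adjusted p = 6.36e-25, and adjusted p = 0.000195 with an estimated correlation). After PMEPA1 they included JUNB, an AP-1 subunit (-0.81), the inhibitors of TGF-beta signalling SMAD7 (-0.73) and SKIL (-0.62), and ID2 (-0.60). KLF10, an early gene induced by TGF-beta, fell by 0.83. Among collagens and extracellular matrix genes 3 of 39 (3 adjusted over the list alone) fell, COL5A1 (-0.81), COL4A1 (-0.68) and COL4A2 (-0.38), and none rose (adjusted p = 9.01e-05, and adjusted p = 0.0254 with an estimated correlation).

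Cholesterol synthesis genes were higher as a list, 6 of 23 (12 adjusted over the list alone) of them past the threshold (adjusted p = 1.36e-13, and adjusted p = 0.0146 with an estimated correlation). Besides enzymes of the pathway this list holds the regulators INSIG1 and SREBF2 and the fatty acid desaturase genes FADS2 and SCD, so it is wider than its name. INSIG1, the endoplasmic reticulum (ER) protein that retains the sterol-regulated transcription factors, rose by 0.59, the desaturase gene FADS2 by 0.44, DHCR7, the last enzyme of the pathway, by 0.34 and the transcription factor gene SREBF2 by 0.33. Of the unfolded protein and amino acid stress genes 4 of 30 (8 adjusted over the list alone) rose (adjusted p = 6.19e-07, and adjusted p = 0.075 with an estimated correlation), namely CRELD2 (0.50), SDF2L1 (0.39), MANF (0.31) and TRIB3 (0.24). Goblet and club cell markers rose in 4 of 20 (7 adjusted over the list alone; adjusted p = 0.000223, and adjusted p = 0.0593 with an estimated correlation): BPIFA1, AGR2 (0.69), a disulfide isomerase of mucus-secreting cells, BPIFB1 (0.35) and the mucin gene MUC5AC (0.30). Alveolar type II cell markers rose in 2 of 16 (4 adjusted over the list alone), CEBPA by 0.31 and LPCAT1 by 0.24 (adjusted p = 0.00918, and adjusted p = 0.124 with an estimated correlation).

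Of the type I interferon response genes 2 of 32 (5 adjusted over the list alone) rose, IFIT1 by 0.45 and PARP9 by 0.26 (adjusted p = 0.000736, and adjusted p = 0.075 with an estimated correlation). IFIT1 did not pass with centring or with either quantile normalization. Of the NRF2 targets 2 of 27 members rose and 1 fell (2 and 1 adjusted over the list alone), with ABCC2 at 0.39, SRXN1 at 0.25 and HMOX1 at -0.52, and the list was higher (adjusted p = 2.24e-05, and adjusted p = 0.277 with an estimated correlation). The oxidative phosphorylation list was higher with a median of 0.071 and no member past the threshold (0 adjusted over the list alone; adjusted p = 0.00408, and adjusted p = 0.523 with an estimated correlation). S phase genes were lower as a list, UHRF1 (-0.36) being the only member of 37 past the threshold (3 adjusted over the list alone), with adjusted p = 6.19e-07, and adjusted p = 0.258 with an estimated correlation. G2 and mitosis genes were lower with 1 of 40 past (1 adjusted over the list alone), KIF23 (-0.34), with adjusted p = 1.89e-05, and adjusted p = 0.373 with an estimated correlation. YAP and TEAD targets were lower with 2 of 22 (3 adjusted over the list alone) past, GADD45B (-0.46) and FOXF2 (-0.35), with adjusted p = 0.000736, and adjusted p = 0.277 with an estimated correlation.

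The other 16 lists did not pass in A549 at 24 h. Notch receptors ligands and cofactors had 0 higher and 1 lower of 34 (0 and 1 adjusted over the list alone; adjusted p = 0.458). Gamma-secretase complex had 0 higher and 0 lower of 5 (1 and 0 adjusted over the list alone; adjusted p = 0.186). Gamma-secretase substrates had 3 higher and 1 lower of 33 (3 and 1 adjusted over the list alone; adjusted p = 0.673). Inflammatory cytokines and chemokines had 1 higher and 1 lower of 27 (1 and 1 adjusted over the list alone; adjusted p = 0.931). Epithelial-mesenchymal transition had 1 higher and 1 lower of 26 (1 and 3 adjusted over the list alone; adjusted p = 0.931). p53 targets had 0 higher and 0 lower of 27 (1 and 0 adjusted over the list alone; adjusted p = 0.931). Hypoxia and glycolysis had 1 higher and 2 lower of 33 (4 and 2 adjusted over the list alone; adjusted p = 0.617). Immediate early genes had 1 higher and 4 lower of 29 (3 and 7 adjusted over the list alone; adjusted p = 0.0564). Aryl hydrocarbon and drug metabolism had 4 higher and 1 lower of 20 (4 and 2 adjusted over the list alone; adjusted p = 0.051). Glucocorticoid and cAMP response had 0 higher and 1 lower of 16 (3 and 2 adjusted over the list alone; adjusted p = 0.271). Neuroendocrine markers had 1 higher and 1 lower of 18 (1 and 1 adjusted over the list alone; adjusted p = 0.315). Ciliated cell markers had 0 higher and 0 lower of 16 (0 and 0 adjusted over the list alone; adjusted p = 0.451). Basal cell and keratin markers had 0 higher and 0 lower of 12 (0 and 1 adjusted over the list alone; adjusted p = 0.896). Fibroblast markers had 0 higher and 0 lower of 15 (0 and 0 adjusted over the list alone; adjusted p = 0.931). Leukocyte and endothelial markers had 0 higher and 0 lower of 18 (0 and 0 adjusted over the list alone; adjusted p = 0.882). Ribosomal proteins had 0 higher and 0 lower of 27 (0 and 0 adjusted over the list alone; adjusted p = 0.838). Among their members, JAG2 fell by 0.33, NRG1 by 0.47, the vitamin D 24-hydroxylase gene CYP24A1 by 0.76, SGK1 by 0.51 and IL11 by 0.51. IL6R rose by 0.45, CXCL16 by 0.40, CCL20 by 0.49, KRT19 by 0.62, CYP4F11 by 0.53 and AHRR by 0.44. IL6 differed by 0.076 ± 0.10 and CXCL8 by 0.14 ± 0.099, neither past the threshold. Mean, median and test differed in sign for the cytokine, transition, basal, fibroblast, leukocyte and ribosomal lists.

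With a difference of at least 0.58 required as well, 64 genes passed, 24 higher and 40 lower. The count was 866 without 4 arrays that stand apart in intensity or 3' to 5' ratio, none of them from this comparison, and 1169 with arrays weighted by their spread. Besides IFIT1, MUC5AC did not pass with either quantile normalization, and KIF23, TRIB3, LPCAT1, TNFRSF1A and PHLDA1 did not pass with centring.

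**Figure D2:**
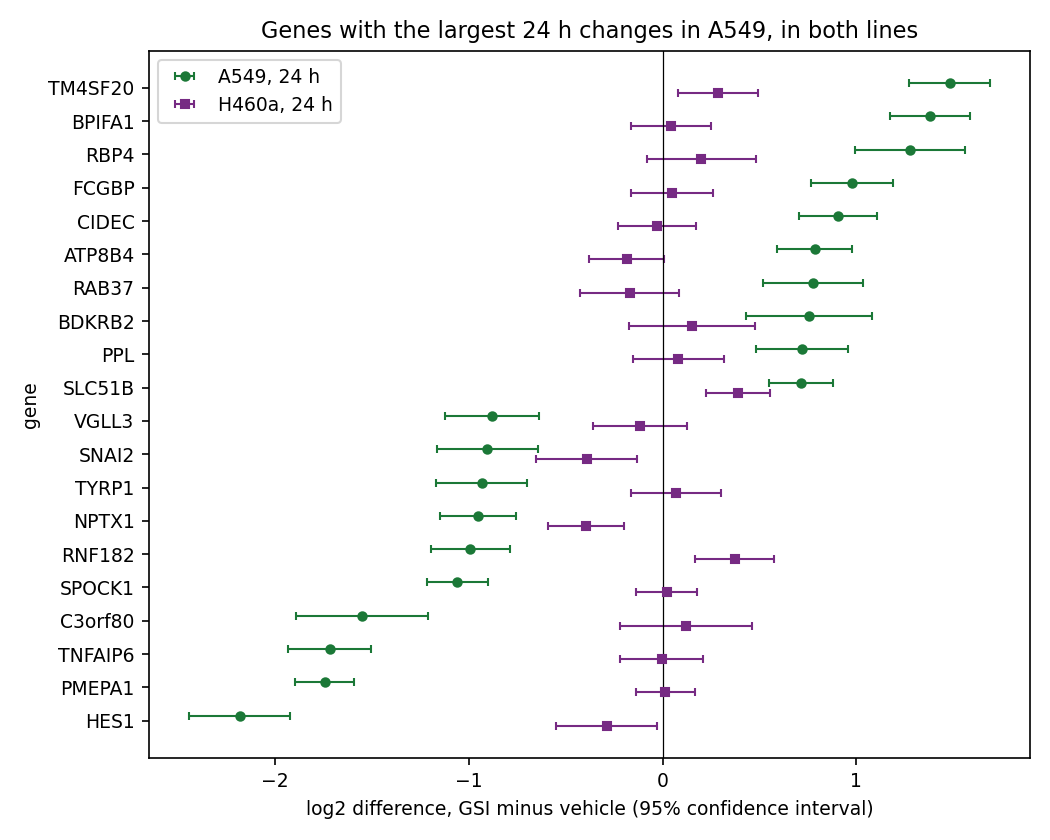
Log2 differences at 24 h, GSI minus vehicle (horizontal axis), of the 10 genes with the largest rise and the 10 with the largest fall in A549 (vertical axis), with green circles for A549, purple squares for H460a and bars for 95% confidence intervals, 4 arrays per group. HES1 lies at -2.18 in A549 and -0.29 in H460a, and TM4SF20 at 1.48 and 0.29.

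The same comparison at 6 h in A549 shows the transcripts that differed early. HES1 fell by 1.63 ± 0.13, from 9.63 ± 0.042 in vehicle (adjusted p = 8.67e-10; 95% confidence interval -1.89 to -1.37), HES4 fell by 0.46 ± 0.10 and HEY1 by 0.41 ± 0.078. LBH, a transcription cofactor gene, fell by 0.81 ± 0.098 (adjusted p = 1.13e-05), JUNB by 0.71 ± 0.066 (adjusted p = 4.08e-08), SNAI2 by 0.68 ± 0.13 and SNAI1, which encodes the related repressor Snail, by 0.62 ± 0.084. GPAT3, an acyltransferase of lipid synthesis, rose by 0.75 ± 0.11 (adjusted p = 0.000112) and ID2, an inhibitor of basic helix-loop-helix factors, by 0.62 ± 0.085 (adjusted p = 5.96e-05).

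In this comparison 2600 genes passed the threshold, 2301 higher and 299 lower, with a median size of 0.30. The GSI group holds arrays 3 and 4, at mean intensities of 589 and 583, against 468 to 496 in the 4 vehicle arrays. With quantile normalization over all 32 arrays 558 genes passed, 265 higher and 293 lower, and with quantile normalization within each line 442, 208 higher and 234 lower. The count was 32 without the 4 arrays that stand apart, 29 with the 8 arrays of the comparison alone and 33 with a difference of at least 0.58. Of the 100 named genes past the threshold, 63 did not pass with quantile normalization over all arrays, among them SLC16A7, NUF2, ECT2, TOP2A, HSPA5, SCD, RPL30, RPL37, GCLM, TXNRD1, E2F8 and PCNA. Leaving out a single array gave 167 genes without GSI array 3, 312 without GSI array 4 and 499 without vehicle array 3. HES1, HEY1, HES4, LBH, JUNB, SNAI1, SNAI2, PMEPA1, ANGPTL4, ID2, GPAT3, IL6R, HERPUD1, GDF15 and AGR2 were the 15 of 100 named genes past the threshold that also passed without the arrays that stand apart. Of these 15, GDF15 (0.37, and 0.20 with quantile normalization over all arrays) and AGR2 (0.43, and 0.18) did not pass with either quantile normalization.

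Other large rises were those of the polarity gene PARD6B (0.89), the integrin gene ITGB8 (0.88), ETV1 (0.74), PLD5 (0.72), GATM (0.71), SLC16A7 (0.63), the noncoding RNA gene JPX (0.62) and NCKAP5 (0.60). In vehicle ITGB8 (5.28) lay near the background, so the size of its rise is a lower limit. NCKAP5 lay near the background in both groups (4.10 and 4.71), so the size of its difference carries little information. ZNF548 (-0.80), DYNLT2 (-0.66), VWA3A (-0.62) and HPGDS (-0.54) fell. Of the 14 genes named by size that have other probe sets, 10 had all of these in the same direction, and PARD6B, ITGB8, GATM and ZNF548 did not. Of the Notch pathway targets 3 of 31 members rose and 5 fell (5 and 5 adjusted over the list alone), and the list did not pass (adjusted p = 0.0532). NRARP differed by -0.048 ± 0.067, HEYL by -0.027 ± 0.11, NOTCH3 by 0.16 ± 0.079, MYC by 0.14 ± 0.063, CCND1 by 0.05 ± 0.079 and JAG1 by 0.30 ± 0.10, none past the threshold, and no gene of the gamma-secretase complex passed. IL6 fell by 0.40 and CCL2 by 0.43, and both also passed with quantile normalization but not without the arrays that stand apart. CXCL8, at 0.38, and CXCL5, at 0.47, passed as deposited but not with quantile normalization.

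Of the TGF-beta response genes 3 of 27 members rose and 4 fell (3 and 4 adjusted over the list alone) at 6 h, with JUNB, ANGPTL4 (-0.58) and PMEPA1 (-0.58) among the falls and ID2 among the rises (median -0.071, and -0.18 with quantile normalization over all arrays; adjusted p = 0.00963, and adjusted p = 0.358 with an estimated correlation). G2 and mitosis genes rose in 17 of 40 (26 adjusted over the list alone), NUF2 by 0.42, ECT2 by 0.42 and TOP2A by 0.35 (median 0.20, and 0.049 with quantile normalization over all arrays; adjusted p = 1.59e-08, and adjusted p = 0.256 with an estimated correlation). Of the 13 lists past the threshold in this comparison, these 2 also passed under both quantile normalizations. Unfolded protein and amino acid stress genes rose in 12 of 30 (14 adjusted over the list alone), with CTH (0.52), DNAJB9 (0.47), HERPUD1 (0.41) and HSPA5 (0.39) at the top (median 0.17, and 0.0067 with quantile normalization over all arrays; adjusted p = 3.05e-06, and adjusted p = 0.203 with an estimated correlation). Cholesterol synthesis genes rose in 8 of 23 (14 adjusted over the list alone), INSIG1 by 0.41 and SCD by 0.33 (median 0.16, and 0.013 with quantile normalization over all arrays; adjusted p = 0.000245, and adjusted p = 0.225 with an estimated correlation).

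Large housekeeping groups were higher in A549 at 6 h as well. Ribosomal protein genes rose in 22 of 27 (25 adjusted over the list alone; median 0.24, and 0.0085 with quantile normalization over all arrays; adjusted p = 1.08e-13, and adjusted p = 0.203 with an estimated correlation), RPL30 by 0.32 and RPL37 by 0.31. Oxidative phosphorylation genes rose in 20 of 30 (24 adjusted over the list alone), and their median turned negative under quantile normalization (median 0.24, and -0.009 with quantile normalization over all arrays; adjusted p = 3.89e-11, and adjusted p = 0.203 with an estimated correlation). NRF2 targets rose in 19 of 27 (20 adjusted over the list alone), GCLM by 0.43 and TXNRD1 by 0.37, while HMOX1 fell by 0.45 (median 0.25, and 0.014 with quantile normalization over all arrays; adjusted p = 1.59e-08, and adjusted p = 0.203 with an estimated correlation). S phase genes rose in 10 of 37 (13 adjusted over the list alone), E2F8 by 0.34 and PCNA by 0.32 (median 0.16, and 0.0048 with quantile normalization over all arrays; adjusted p = 0.00247, and adjusted p = 0.455 with an estimated correlation). Hypoxia and glycolysis genes rose in 12 of 33 (16 adjusted over the list alone) and ANGPTL4 fell, with a median and test that turned to the other sign under quantile normalization (median 0.14, and -0.046 with quantile normalization over all arrays; adjusted p = 0.00963, and adjusted p = 0.455 with an estimated correlation). YAP and TEAD targets rose in 7 of 22 (10 adjusted over the list alone) and fell in 1 (1 adjusted over the list alone; median 0.18, and 0.025 with quantile normalization over all arrays; adjusted p = 0.023, and adjusted p = 0.455 with an estimated correlation). Glucocorticoid and cAMP response genes rose in 7 of 16 (8 adjusted over the list alone), CITED2 by 0.56 (median 0.25, and 0.11 with quantile normalization over all arrays; adjusted p = 0.0133, and adjusted p = 0.203 with an estimated correlation). Fibroblast markers were lower with 0 of 15 past (0 adjusted over the list alone; median -0.075, and -0.096 with quantile normalization over all arrays; adjusted p = 0.0402, and adjusted p = 0.203 with an estimated correlation). Leukocyte and endothelial markers were lower with CD79A (-0.24) as 1 of 18 past (0 adjusted over the list alone; median -0.084, and -0.071 with quantile normalization over all arrays; adjusted p = 0.0242, and adjusted p = 0.388 with an estimated correlation).

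**Figure D3:**
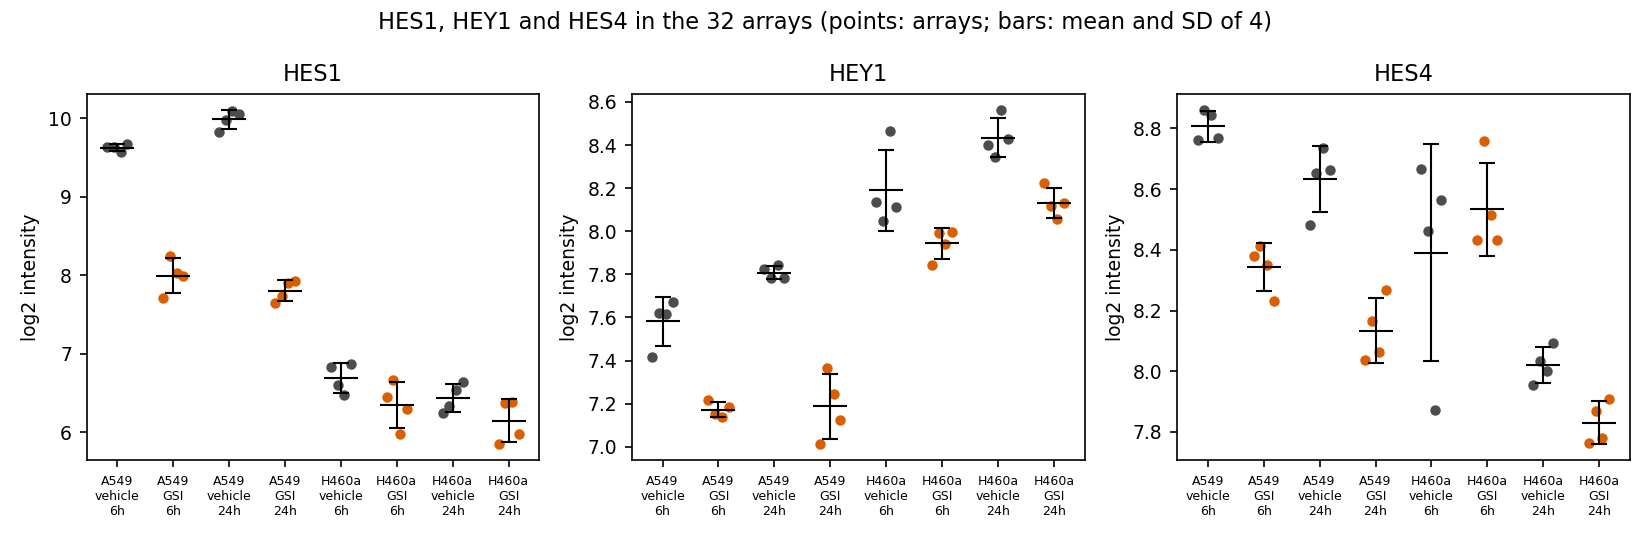
Log2 intensities (vertical axes, not starting at 0) of the Notch target genes HES1, HEY1 and HES4 in the 8 groups, with grey points for vehicle arrays, orange points for GSI arrays and bars for the mean and SD of 4. HES1 in A549 lies at 9.98 ± 0.12 in vehicle and 7.80 ± 0.14 with GSI at 24 h, and in H460a at 6.44 ± 0.18 and 6.15 ± 0.27.

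In H460a at 6 h the same question was put to the second line. HERPUD1, a membrane protein of ER-associated degradation, rose by 0.78 ± 0.065, from 11.03 ± 0.13 to 11.82 ± 0.015 (adjusted p = 3.42e-09). DNAJB9, an ER co-chaperone, rose by 0.86 ± 0.09 (adjusted p = 7.05e-07) and SDF2L1, another ER protein, by 0.54 ± 0.087 (adjusted p = 0.00277). The adhesion gene CEACAM6 fell by 0.48 ± 0.091, from 6.05 ± 0.13 (adjusted p = 0.016). HES1 differed by -0.35 ± 0.13 (adjusted p = 0.324), HEY1 by -0.25 ± 0.078 and HES4 by 0.14 ± 0.10, none past the threshold.

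In this comparison 19 genes passed, 14 higher and 5 lower, and 2201 had an unadjusted p under 0.05. The other rises named were those of CCNG2 (0.52), the stress-induced secreted factor GDF15 (0.46), SLC33A1 (0.43), DNAJC3 (0.43), ALG2 (0.40), VASN (0.39), INSIG1 (0.39) and the glucose transporter gene SLC2A3 (0.32). TMEM74B (-0.43), OR51B2 (-0.41) and PSAPL1 (-0.36) fell. CDH1, which encodes E-cadherin, passed at -0.57, but its levels of 4.80 ± 0.15 and 4.23 ± 0.19 both lie near the background, so the size of this difference carries little information. Of the 10 genes named by size that have other probe sets, 6 had all of these in the same direction, and HERPUD1, CCNG2, GDF15 and DNAJC3 did not. GDF15, SLC2A3 and TMEM74B did not pass with quantile normalization. Vehicle array 3, the array with the high 3' to 5' ratio, held the lowest vehicle values of SDF2L1, GDF15 and VASN, by a wide gap. NOTCH3 differed by -0.24 ± 0.079, NRARP by -0.0052 ± 0.067, MYC by -0.011 ± 0.063 and PSENEN by 0.62 ± 0.24, none past the threshold. Without vehicle array 3 the PSENEN difference was 0.30.

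Unfolded protein and amino acid stress genes rose in 4 of 30 (9 adjusted over the list alone), which were DNAJB9, HERPUD1, SDF2L1 and DNAJC3 (adjusted p = 1.85e-11, and adjusted p = 0.0583 with an estimated correlation). Cholesterol synthesis genes rose in 1 of 23 (6 adjusted over the list alone), INSIG1 (adjusted p = 4.25e-08, and adjusted p = 0.123 with an estimated correlation). Hypoxia and glycolysis genes rose in 1 of 33 (1 adjusted over the list alone), SLC2A3 (adjusted p = 0.00587, and adjusted p = 0.861 with an estimated correlation), and as a list did not pass with quantile normalization. Immediate early genes were higher with a median of 0.07 and none of 29 past (1 adjusted over the list alone; adjusted p = 0.000713, and adjusted p = 0.449 with an estimated correlation). Ribosomal protein genes were higher with a median of 0.045 and none of 27 past (0 adjusted over the list alone; adjusted p = 0.00745, and adjusted p = 0.917 with an estimated correlation). The Notch pathway targets had a median of 0.0065 and none past (adjusted p = 0.812), with a test that leaned lower. The count of genes was 46 without the 4 arrays that stand apart, 110 with array weights, 2 with the 8 arrays of the comparison alone, 46 without vehicle array 1 and 9 without GSI array 4.

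In H460a at 24 h, TTC17 was the gene past the threshold and rose by 0.42 ± 0.071, from 9.69 ± 0.027 to 10.11 ± 0.071 (adjusted p = 0.031). Of its 5 other probe sets 3 were higher and the others lower, from -0.11 to 0.37, and none passed. TTC17 did not pass with centring. HES1 differed by -0.29 ± 0.13 (adjusted p = 0.823; 95% confidence interval -0.55 to -0.028), HEY1 by -0.30 ± 0.078 and HES4 by -0.19 ± 0.10. MYC differed by -0.041 ± 0.063, NOTCH3 by -0.12 ± 0.079, IL6 by -0.18 ± 0.10 and CXCL8 by 0.11 ± 0.099. No gene of the Notch pathway targets passed (1 lower adjusted over the list alone, and adjusted p = 0.335 for the list). Of all 19775 genes 1145 had an unadjusted p under 0.05 in limma, little above the share of 0.05 that chance alone gives.

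No member of any list passed on its own in H460a at 24 h, but 6 lists differed from other genes, and 4 of them did so without the 4 arrays that stand apart. GSI array 3, at the lowest mean intensity of the H460a arrays (570), is among those 4 arrays, and it holds the lowest GSI values of ECT2 (10.67), NUF2 (10.03) and KIF23 (9.54), 3 mitotic genes. G2 and mitosis genes were lower, with a median of -0.096 and -0.044 without the arrays that stand apart (0 adjusted over the list alone; adjusted p = 1.24e-07, and adjusted p = 0.615 with an estimated correlation). S phase genes were lower, with a median of -0.093 and -0.06 without those arrays (1 lower adjusted over the list alone; adjusted p = 2.1e-07, and adjusted p = 0.615 with an estimated correlation). Cholesterol synthesis genes were higher, with medians of 0.11 and 0.12 (1 higher adjusted over the list alone; adjusted p = 2.1e-07, and adjusted p = 0.36 with an estimated correlation). Unfolded protein and amino acid stress genes were higher, with medians of 0.029 and 0.063 (0 adjusted over the list alone; adjusted p = 0.0266, and adjusted p = 0.666 with an estimated correlation). YAP and TEAD targets, with medians of -0.087 and -0.041 (2 lower adjusted over the list alone; adjusted p = 0.00459, and adjusted p = 0.666 with an estimated correlation), did not pass without those arrays. Hypoxia and glycolysis genes, with medians of -0.043 and -0.021 (0 adjusted over the list alone; adjusted p = 0.0266, and adjusted p = 0.666 with an estimated correlation), did not pass without them either. The gene count was 11 without the 4 arrays that stand apart and 25 with technical covariates. It was 0 without vehicle array 1 or 2 or GSI array 2, 3 or 4, and 3 without vehicle array 4.

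**Figure D4:**
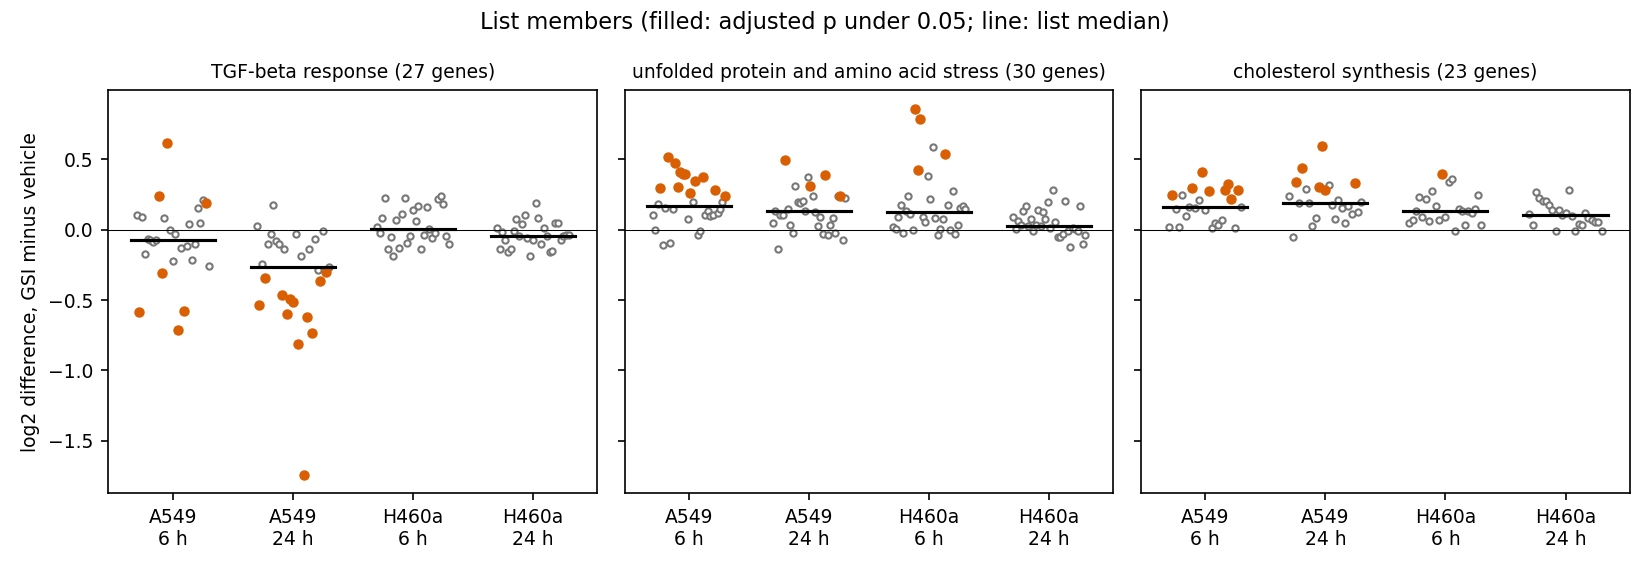
Log2 differences, GSI minus vehicle (vertical axis), of the measured members of 3 lists in the 4 comparisons (horizontal axis), with filled orange points for genes past the threshold, open points for the others and black lines for list medians. The TGF-beta response median is -0.27 in A549 at 24 h, and the cholesterol synthesis medians are 0.16, 0.19, 0.13 and 0.11 from left to right.

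Averaged over both lines and both times, HES1 fell by 1.11 ± 0.064 (adjusted p = 1.5e-13), PMEPA1 by 0.59 ± 0.037, TNFAIP6 by 0.56 ± 0.053, SNAI2 by 0.48 ± 0.064 and C3orf80 by 0.45 ± 0.083. In H460a TNFAIP6 (4.65 to 4.90) and C3orf80 (3.72 to 3.86) lay near the background, as did C3orf80 with GSI in A549, so their averages do not measure a fall in both lines. HES1, PMEPA1 and SNAI2 did not pass in H460a at either time, so their averages do not show a fall in both lines either. There PMEPA1 lay at 8.35 in vehicle and 8.31 with GSI at 6 h, and at 7.661 and 7.675 at 24 h. SNAI2 lay at 7.64 and 7.68 at 6 h, and at 7.98 and 7.59 at 24 h. TM4SF20 rose by 0.59 ± 0.051, DNAJB9 by 0.42 ± 0.045, BDKRB2 by 0.39 ± 0.08, the complement receptor gene C5AR1 by 0.38 ± 0.06 and INSIG1 by 0.38 ± 0.039. Of the cholesterol synthesis genes 13 of 23 (21 adjusted over the list alone) rose (adjusted p = 6.13e-21, and adjusted p = 0.00255 with an estimated correlation). Of the unfolded protein and amino acid stress genes 15 of 30 (16 adjusted over the list alone) rose (adjusted p = 1.54e-17, and adjusted p = 0.00401 with an estimated correlation). Of the TGF-beta response genes 6 of 27 (9 adjusted over the list alone) fell (adjusted p = 9.59e-12, and adjusted p = 0.00765 with an estimated correlation). In all 432 genes passed, 353 higher and 79 lower, against 184 higher and 170 lower with quantile normalization over all arrays and 176 and 158 within each line. Leaving out A549 GSI array 1 at 6 h gave 885 genes, H460a vehicle array 3 at 6 h 666 and H460a GSI array 3 at 24 h 890.

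The GSI effect was tested for a difference between the lines, as the effect in A549 minus that in H460a. At 24 h the difference was -1.90 ± 0.18 for HES1 (adjusted p = 4.78e-08), -1.76 ± 0.11 for PMEPA1 (adjusted p = 4.84e-13) and -1.71 ± 0.15 for TNFAIP6 (adjusted p = 6.74e-09). It was -1.67 for C3orf80, -1.36 for RNF182, 1.33 for BPIFA1, 1.20 for TM4SF20, 1.08 for RBP4, 0.97 for ATP8B4 and 0.95 for RAB37. In H460a vehicle arrays C3orf80 (3.72), RNF182 (4.26) and TNFAIP6 (4.65) lay near the background, which leaves little room for a fall, and RNF182 lay at 4.63 with GSI. HES1 lay at 6.44 in H460a vehicle, against 9.98 in A549 vehicle, so it had less room to fall in H460a. Of the TGF-beta response genes 4 of 27 (12 adjusted over the list alone) were lower in this difference (adjusted p = 3.69e-15, and adjusted p = 0.00481 with an estimated correlation). In all 126 genes passed, 72 with a higher and 54 with a lower difference, and 74 and 83 with quantile normalization within each line. Without A549 vehicle array 1 or 2, A549 GSI array 2 or 3, or H460a vehicle array 2, the counts were 72, 81, 75, 78 and 82.

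At 6 h the difference between the lines was -1.29 ± 0.18 for HES1 (adjusted p = 0.000299), -1.04 ± 0.14 for LBH and -0.88 ± 0.094 for JUNB (adjusted p = 2.08e-06). It was -0.59 for SNAI1, -0.56 for ANGPTL4, 0.92 for PLD5, 0.87 for NR5A2, 0.84 for CDH1, 0.82 for GPAT3 and 0.71 for ID2. In H460a vehicle arrays PLD5 (4.22), CDH1 (4.80) and NR5A2 (5.33) lay near the background, and NR5A2 did not pass with quantile normalization. HES1 lay at 6.69 in H460a vehicle, against 9.63 in A549 vehicle, so it had less room to fall in H460a. In all 24 genes passed, 17 with a higher and 7 with a lower difference, against 17 and 23 with quantile normalization over all arrays and 15 and 19 within each line. The count was 844 without A549 GSI array 1, 180 without A549 GSI array 2, 15 without A549 GSI array 3 and 15 without H460a GSI array 4.

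The GSI effect was also compared between the times, as the effect at 24 h minus that at 6 h. In A549 the difference was -1.21 ± 0.12 for ID2 (adjusted p = 1.22e-07), which rose by 0.62 at 6 h and fell by 0.60 at 24 h. It was 1.51 ± 0.14 for BPIFA1, -1.45 ± 0.15 for TNFAIP6, -1.16 ± 0.11 for PMEPA1 (adjusted p = 3.77e-08) and -1.27 for C3orf80, which lay near the background in 3 of the 4 groups. RNF182 had a difference of -1.10, RBP4 of 1.18, TM4SF20 of 1.05, CIDEC of 0.92 and ZNF236 of 0.90. ZNF236 lay at 10.19 in vehicle and 9.38 ± 0.69 with GSI at 6 h, and at 8.73 and 8.82 at 24 h. The 6 h arrays differ in mean intensity, so for ZNF236 a change of the effect with time cannot be told apart from array intensity. In all 733 genes passed, 130 with a higher and 603 with a lower difference, against 228 and 199 with quantile normalization over all arrays and 173 and 166 within each line. Without the 4 arrays that stand apart, which include A549 GSI arrays 3 and 4 at 6 h, 104 genes passed. Leaving out 1 array in turn gave from 103 genes (without A549 vehicle array 3 at 6 h) to 1948 (without A549 GSI array 1 at 6 h). For 13 of 16 arrays the count moved by more than 1.5 times. In H460a the genes past the threshold were DNAJB9, with a difference of -0.82 ± 0.13 (adjusted p = 0.00277), and HERPUD1, with -0.76 ± 0.091 (adjusted p = 3.65e-05).

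Vehicle arrays at 24 h were compared with those at 6 h to show the change with time in culture. In H460a TXNIP, an inhibitor of thioredoxin whose gene responds to glucose, rose by 2.67 ± 0.093 (adjusted p = 4.13e-20), and PDK4, a kinase that inhibits pyruvate dehydrogenase, by 2.04 ± 0.10. NRN1 rose by 2.37, SPAG4 by 2.21, PPL by 2.13, HAL by 2.06, PPFIA4 by 1.99 and LINC00189, from a level near the background (5.18), by at least 1.91. The chemokine gene CXCL2 fell by 1.77 ± 0.12, ID3 by 1.54 ± 0.066, the tubulin gene TUBB2A by 1.52, GPATCH4 by 1.44 and NOP16, a ribosome assembly factor, by 1.33. SLC29A1 fell by 1.40, ERVMER34-1 by 1.38 and the replication gene GINS4 by 1.38. S phase genes fell in 36 of 37 (37 adjusted over the list alone; adjusted p = 4.67e-31, and adjusted p = 0.0193 with an estimated correlation). Hypoxia and glycolysis genes rose in 25 of 33 (25 adjusted over the list alone; adjusted p = 5.33e-21, and adjusted p = 0.0193 with an estimated correlation). Collagens and extracellular matrix genes rose in 14 of 39 (14 adjusted over the list alone) and fell in 1 (2 adjusted over the list alone; adjusted p = 0.000411, and adjusted p = 0.0429 with an estimated correlation). G2 and mitosis genes fell in 34 of 40 (36 adjusted over the list alone; adjusted p = 6.45e-18, and adjusted p = 0.0693 with an estimated correlation). In all 6004 genes passed, 2980 higher and 3024 lower.

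In A549 vehicle arrays, the fibrinogen gene FGG rose by 1.72 ± 0.11 between 6 and 24 h (adjusted p = 8.57e-13), and CHGB, which encodes a protein of secretory granules, by 1.67 ± 0.14. ITGB8 rose by at least 1.74 from a level near the background (5.28). NHERF2 rose by 1.61, PLD5 by 1.55, RASSF9 by 1.52, GASK1B by 1.49 and IGFBP1 2.83-fold. ZNF548 fell by 1.44 ± 0.15, LINC00520 by 1.14, TCP11L2 by 1.05, VWA3A by 1.02, DYNLT2 by 0.98, GNAO1 by 0.96 and CARD16, to a level near the background (4.61), by at least 0.94. The A549 GSI arrays at 6 h differ in mean intensity. In them ZNF548 (9.18 ± 0.48), LINC00520 (9.75 ± 0.55), TCP11L2 (7.28 ± 0.575) and VWA3A (7.92 ± 0.37) lay between the vehicle groups. In H460a vehicle ZNF548 lay at 8.74 at 6 h and 8.87 at 24 h, near the 8.54 of A549 vehicle at 24 h. So for these falls a change with time cannot be told apart from array intensity. ZNF236 fell by 1.46 ± 0.17, but its other probe set rose by 0.63. Of the 12 genes named here that have other probe sets, 6 had all of these in the same direction. YAP and TEAD targets rose in 18 of 22 (18 adjusted over the list alone; median 0.45, and 0.15 with quantile normalization; adjusted p = 2.05e-05, and adjusted p = 0.21 with an estimated correlation). Cholesterol synthesis genes rose in 17 of 23 (17 adjusted over the list alone; median 0.31, and 0.049 with quantile normalization; adjusted p = 2.43e-05, and adjusted p = 0.21 with an estimated correlation). In all 8731 genes passed, 5766 higher and 2965 lower. With the array's log2 SD and beta-actin 3' to 5' difference as covariates 541 passed, though this SD itself differs between the 6 h and 24 h arrays. The 6 h arrays lay at mean intensities of 468 to 496 and the 24 h arrays at 584 to 597, and the split was 3276 higher and 4371 lower with quantile normalization over all arrays, 3228 and 4283 within each line and 6405 and 1902 with arrays centred on their medians.

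A549 and H460a were compared in vehicle, as the mean over both times of A549 minus H460a. The Wnt inhibitor gene DKK1 was higher in A549 by 7.31 ± 0.087, whereas KRT19, a keratin gene, was lower at -6.93 ± 0.077, as was the cadherin gene CDH11 at -6.83 ± 0.11. CYP24A1, the imprinted gene PEG10, MARCKS, BICC1, IGFBP1, NRP1 and TCIM were also higher in A549. Their measured differences were 8.58, 7.47, 7.30, 7.12, 7.11, 7.11 and 7.03. The collagen gene COL8A1 (-8.55), EPB41L3 (-8.45), the peroxidase gene PRDX2 (-8.21), GDA (-7.76), FGF13 (-7.38) and SLITRK4 (-6.93) were lower. In the line with the lower level these 13 genes lay near the background, with vehicle group means from 3.55 (TCIM) to 5.21 (NRP1), so the sizes are lower limits and their order carries no information. The adjusted p-values of the 16 genes ran from 2.88e-42 to 4.36e-32. Of the TGF-beta response genes 17 of 27 were higher in A549 and 5 lower (17 and 5 adjusted over the list alone; adjusted p = 0.000567, and adjusted p = 0.388 with an estimated correlation). G2 and mitosis genes were lower in 38 of 40 (38 adjusted over the list alone; adjusted p = 3.77e-17, and adjusted p = 0.257 with an estimated correlation). In all 11205 genes passed, 5689 higher and 5516 lower in A549.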

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

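In this part the tests chosen only after the result was seen are that of the HES1 fall without GSI arrays 3 and 4, both tests of H460a vehicle array 3 at 6 h, and the values without the arrays that stand apart or by scaling. A single array lay far from the other 3 of its group, by the Dixon gap test, for 3 of 24 array measures and for 32 of 695 sets of 4 values of a named gene. Chance alone picks out about 1 in 20 groups. The array measures were the mean intensity of H460a vehicle array 2 at 24 h (593) and the beta-actin 3' to 5' difference of A549 vehicle array 1 (0.21) and H460a vehicle array 3 (2.19) at 6 h.

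The arrays with more than 1 such log2 value were H460a vehicle array 3 at 6 h with COL8A1 (13.39), GDF15 (9.14), KRT19 (12.89), NRARP (8.37), SDF2L1 (10.29), SLC29A1 (9.21), TNFAIP6 (4.67) and VASN (8.43), A549 vehicle array 4 at 6 h with CEBPA (8.71), GDF15 (10.98), HPGDS (6.23) and TNFAIP6 (5.91), H460a vehicle array 3 at 24 h with APH1A (11.30) and PSENEN (9.65), A549 vehicle array 1 at 24 h with C3orf80 (6.12) and NCSTN (10.01), A549 vehicle array 2 at 24 h with DYNLT2 (6.63) and ID2 (11.83), A549 vehicle array 4 at 24 h with IL6 (6.03) and SPOCK1 (9.46), A549 GSI array 4 at 24 h with MANF (11.17) and SNAI2 (5.35), and H460a GSI array 4 at 6 h with MYC (12.45) and PMEPA1 (8.26). In A549 the single values were AGR2 (13.70) in A549 GSI array 1 at 24 h, ANGPTL4 (8.95) in A549 GSI array 1 at 6 h, BDKRB2 (10.40) in A549 vehicle array 2 at 6 h, JAG2 (8.40) in A549 vehicle array 3 at 24 h, MARCKS (11.25) in A549 vehicle array 1 at 6 h and TRIB3 (10.85) in A549 GSI array 2 at 24 h. In H460a they were CXCL8 (12.36) in H460a GSI array 3 at 24 h and HERPUD1 (11.79) in H460a GSI array 1 at 6 h.

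The GSI effect differed between the lines, by a test of the difference itself, for 24 genes at 6 h and 126 at 24 h. At 6 h the named genes were PLD5 (0.92), NR5A2 (0.87), CDH1 (0.84), GPAT3 (0.82), ID2 (0.71), HES1 (-1.29), LBH (-1.04), JUNB (-0.88), SNAI1 (-0.59) and ANGPTL4 (-0.56). At 24 h they were BPIFA1 (1.33), TM4SF20 (1.20), RBP4 (1.08), ATP8B4 (0.97), RAB37 (0.95), HES1 (-1.90), PMEPA1 (-1.76), TNFAIP6 (-1.71), C3orf80 (-1.67) and RNF182 (-1.36). Between the times it differed for 733 genes in A549, among them BPIFA1 (1.51), RBP4 (1.18), TM4SF20 (1.05), CIDEC (0.92), ZNF236 (0.90), TNFAIP6 (-1.45), C3orf80 (-1.27), ID2 (-1.21), PMEPA1 (-1.16) and RNF182 (-1.10). In H460a it differed for 2 genes, DNAJB9 (-0.82) and HERPUD1 (-0.76). PLD5, NR5A2 and CDH1 at 6 h and TNFAIP6, C3orf80 and RNF182 at 24 h lay near the background in H460a, so for them a difference between lines can follow from the lack of expression there. HES1 lay lower in H460a vehicle (6.69 at 6 h and 6.44 at 24 h) than in A549 vehicle (9.63 and 9.98), which leaves less room for a fall. The ZNF236 difference between times cannot be told apart from array intensity at 6 h.

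In A549 at 6 h, 2600 genes passed, 2301 of them higher, in a comparison where GSI arrays 3 and 4 have a higher mean intensity than the other 6. Their intensity range could contribute: as the whole cause it should leave the called genes a median difference in GSI arrays 1 and 2 under 1/3 of that in arrays 3 and 4, and otherwise at least 0.67 of it. The medians, in the direction of the call, were 0.161 and 0.427, a ratio of 0.378 (0.370 to 0.384 over genes) between the bounds. The genes were called on these same arrays, 100% with the call's sign in GSI arrays 1 and 2, and are not independent. So range and treatment cannot be told apart for these genes as a set. The hybridization control cre lay at 13.774 to 13.925 in the vehicle arrays and 13.80 and 14.03 in GSI arrays 1 and 2. In GSI arrays 3 and 4 it lay at 14.54 and 14.32, so the gap in intensity was not confined to the cells' transcripts. HES1 (-1.65 without arrays 3 and 4), JUNB (-0.72), LBH (-0.83), PMEPA1, ANGPTL4, SNAI1, GPAT3 and ID2, 8 of the 20 genes named by size, also passed without the arrays that stand apart, which argues against the range as the whole cause of their differences. Of the other 12, 11 passed with both quantile normalizations. These equalize the distributions of the arrays but not effects on single probe sets, so passing them decides nothing here. ITGB8 (0.90) and ZNF548 (-0.97), 2 of the 11, were at 0.56 and -0.41 without the arrays that stand apart and did not pass. Their other probe sets did not all share the direction, and ITGB8 lay near the background in vehicle. ZNF548 lay at 9.98 in A549 vehicle at 6 h, 9.18 ± 0.48 with GSI and 8.54 to 8.87 in the other groups. So for these 12 genes the range, another difference of the arrays and a response to the inhibitor cannot be told apart.

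H460a vehicle array 3 at 6 h lay apart from its group for 8 named gene values. RNA degradation or short cDNA in this array may explain this: the 3' to 5' difference was higher than in each of the other 15 H460a arrays for 3 of 3 control transcripts. A mislabelled time is argued against, as the mean correlation across genes was 0.991 with the other H460a 6 h arrays and 0.984 with the 24 h arrays, a difference of 0.00720. No biological explanation was tested, and the design names none for a single array.

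TGF-beta response genes were lower in A549 at 24 h with a median of -0.27. The intensity range of the arrays is argued against, as their log2 SDs ran from 2.23 to 2.27 in vehicle and from 2.23 to 2.28 with GSI. The list median lay at percentile 0 of 10000 random lists matched on mean level, whose central 95% ran from -0.039 to 0.058. Genes regulated together can lie outside such lists whatever the cause, so this does not bear on the range. Members shared with the matrix, YAP and transition lists do not carry the result, since the median of the other 21 of 27 members was 1.12 times that of the whole list. Of 35 splits of the 8 arrays 1, the real one, gave a median as large in size, and the largest other was 0.15. This is the smallest share possible, and the list is 1 of 29 tested on these arrays. So the splits cannot exclude chance for a list picked among them. A lower TGF-beta response under the inhibitor is a hypothesis, found and tested on the same arrays.

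Other splits of the same arrays were fitted for each count of genes, within the comparison's own arrays, so they speak to the counts given here and not to those of the 32-array model where these differ. Chance is called excluded where a share under 0.05 of the splits gave as many genes, and 1 of 35 is the smallest share possible there. The splits speak to the spread between these arrays, which may be technical. Chance was excluded for A549 at 6 h, where 1 of 35 splits gave as many genes as the real 29 and the highest other gave 1. The same holds for A549 at 24 h (1 of 35; 620, highest other 2). For H460a at 6 h it was excluded for a count of 2 (1 of 35, highest other 0), and not tested for the 19 genes of the 32-array model. It was excluded for the averaged effect (1 of 100, with 432 genes and 18 in the highest other). The splits for differences between lines or times exchanged vehicle and GSI labels within each line and time. They therefore compare with no effect at all and not with an equal effect, so they cannot exclude chance for such a difference. For the difference between lines at 6 h 1 of 100 splits gave as many as the real 11. The highest other, 9, came from a split that kept the 8 A549 arrays and 6 of 8 H460a arrays in their own groups. In H460a at 24 h the real split gave 0 genes in limma, as did the other splits (35 of 35), so chance was not excluded. In the 32-array model 1145 of 19775 genes had an unadjusted p under 0.05, little above the share of 0.05 that chance alone gives. For the difference between lines at 24 h, 3 of 100 splits gave as many as the real 112, and the higher counts, 127 and 143, came from splits that kept the 8 A549 arrays in their own groups. For the difference between times in A549 it was 1 of 100 (817, highest other 118). For that in H460a it was 3 of 100 (2, highest other 6), and the higher count came from a split that exchanged the vehicle and GSI labels of the 8 arrays at 6 h. Chance was excluded for 24 h against 6 h in vehicle A549 (1 of 35; 9416, highest other 0), in vehicle H460a (1 of 35; 5010, highest other 6) and between the lines (1 of 100; 11160, highest other 8426, from a split that kept 14 of 16 arrays in place).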

How the results depend on the processing

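The technical covariates and the values without the arrays that stand apart were chosen after seeing the data; the other alternatives were planned. Counts are of genes past the threshold unless lists are named. Counts of genes, and of lists in the 4 GSI comparisons, that are not given here stayed within 1.5 times the count of the report. The cause was not tested for any of the differences below, except that a required difference of 0.58 and the testing of single probe sets change what is counted. Between lines and between times stand for the differences of the GSI effect. Where H460a at 24 h is at 0 by limma, the 32-array model gave 1145 of 19775 genes with an unadjusted p under 0.05. That is little above the share of 0.05 that chance alone gives. With the comparison's own arrays the counts were A549 at 6 h 29, H460a at 6 h 2, H460a at 24 h 0 and between lines at 6 h 11. With quantile normalization over all arrays the counts were A549 at 6 h 558, H460a at 24 h 2, between lines at 6 h 40, between times in A549 427 and between times in H460a 4. With quantile normalization within each line the counts were A549 at 6 h 442, H460a at 24 h 4, between times in A549 339 and between times in H460a 4. With a difference of at least 0.58 the counts were A549 at 6 h 33, A549 at 24 h 64, H460a at 6 h 2, H460a at 24 h 0, averaged 3, between lines at 24 h 65, between times in A549 154, vehicle A549 1516, vehicle H460a 1383 and between lines in vehicle 4166. With array weights the counts were A549 at 24 h 1169, H460a at 6 h 110, H460a at 24 h 10, averaged 1884, between lines at 6 h 81, between lines at 24 h 283, between times in A549 1852 and between times in H460a 6. With the lines fitted separately the counts were H460a at 6 h 2 and H460a at 24 h 0. With the mean of the probe sets the counts were H460a at 6 h 11, H460a at 24 h 0, between times in A549 409 and between times in H460a 1. With every probe set on its own the counts were H460a at 24 h 0, between times in A549 375, vehicle A549 17533, vehicle H460a 11636 and between lines in vehicle 25805. With arrays centred on their medians the counts were H460a at 24 h 0 and between times in A549 325. Without dim genes the counts were averaged 733, between lines at 6 h 217, between times in A549 1385, A549 at 6 h lists 7 and H460a at 6 h lists 3. With trend and robust it was between lines at 6 h 129. With an estimated correlation in camera the counts were A549 at 6 h lists 0, A549 at 24 h lists 3, H460a at 6 h lists 0 and H460a at 24 h lists 0. In the other contrasts the lists past the threshold went with an estimated correlation from 9 to 3 (averaged), 6 to 0 (between lines at 6 h), 7 to 1 (between lines at 24 h), 11 to 0 (between times in A549), 5 to 0 (between times in H460a), 12 to 0 (vehicle A549), 11 to 3 (vehicle H460a) and 10 to 0 (between lines in vehicle).

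The covariates are the SD of the array's log2 values and the beta-actin 3' to 5' difference, and the arrays that stand apart are A549 GSI arrays 3 and 4 and H460a vehicle array 3 at 6 h and H460a GSI array 3 at 24 h. With technical covariates the counts were A549 at 6 h 28, A549 at 24 h 980, H460a at 24 h 25, between lines at 24 h 288, between times in A549 96, between times in H460a 6 and vehicle A549 541. Without the arrays that stand apart the counts were A549 at 6 h 32, A549 at 24 h 866, H460a at 6 h 46, H460a at 24 h 11, between lines at 6 h 14, between lines at 24 h 289, between times in A549 104 and between times in H460a 6. Lists between lines at 24 h went from 7 to 2 and between lines at 6 h from 6 to 9; in the other contrasts they stayed within 1.5 times.

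The replicate number was also used as a block. Of 16 same-numbered vehicle and GSI pairs 5 correlated over 0.1 after removal of group means, from -0.35 to 0.317, and 6 vehicle arrays correlated best with the GSI array of their number, so the numbers were not taken as pairs. The correlation within blocks was 0.000734 by line and time, -0.0076 by line and treatment and -0.094 by time and treatment. With the replicate block the counts were H460a at 6 h 4, H460a at 24 h 0, between lines at 6 h 10 and between times in A549 237.

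With 1 array left out in turn the counts ran: A549 at 6 h 167 to 3834, A549 at 24 h 293 to 388, H460a at 6 h 9 to 46, H460a at 24 h 0 to 3, averaged 298 to 890, between lines at 6 h 15 to 844, between lines at 24 h 72 to 117, between times in A549 103 to 1948, between times in H460a 2 to 5, vehicle A549 7311 to 8779, vehicle H460a 5454 to 5891, between lines in vehicle 10826 to 11150. Lists: A549 at 6 h 12 to 14, A549 at 24 h 13 to 15, H460a at 6 h 4 to 6, H460a at 24 h 4 to 7. Arrays whose omission moved a count by more than 1.5 times, with the count without them, were as follows. For A549 at 6 h, A549 vehicle 6 h 3 (499), A549 GSI 6 h 3 (167) and A549 GSI 6 h 4 (312). For H460a at 6 h, H460a vehicle 6 h 1 (46) and H460a GSI 6 h 4 (9). For H460a at 24 h, H460a vehicle 24 h 1 (0), H460a vehicle 24 h 2 (0), H460a vehicle 24 h 4 (3), H460a GSI 24 h 2 (0), H460a GSI 24 h 3 (0) and H460a GSI 24 h 4 (0). For the averaged effect, A549 GSI 6 h 1 (885), H460a vehicle 6 h 3 (666) and H460a GSI 24 h 3 (890). For the difference between lines at 6 h, A549 GSI 6 h 1 (844), A549 GSI 6 h 2 (180), A549 GSI 6 h 3 (15) and H460a GSI 6 h 4 (15). For the difference between lines at 24 h, A549 vehicle 24 h 1 (72), A549 vehicle 24 h 2 (81), A549 GSI 24 h 2 (75), A549 GSI 24 h 3 (78) and H460a vehicle 24 h 2 (82). For the difference between times in A549, A549 vehicle 6 h 2 (421), A549 vehicle 6 h 3 (103), A549 vehicle 6 h 4 (325), A549 GSI 6 h 1 (1948), A549 GSI 6 h 2 (1512), A549 GSI 6 h 3 (107), A549 GSI 6 h 4 (114), A549 vehicle 24 h 2 (215), A549 vehicle 24 h 3 (201), A549 vehicle 24 h 4 (281), A549 GSI 24 h 1 (266), A549 GSI 24 h 2 (241) and A549 GSI 24 h 4 (218). For the difference between times in H460a, H460a vehicle 6 h 3 (4), H460a GSI 24 h 1 (5) and H460a GSI 24 h 2 (4).

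Of 334 values of named genes, gene by comparison, 278 passed. Their direction and side of the threshold held for 324 with arrays centred on their medians (8 weaker, 2 moved), for 295 with the replicate block (39 weaker) and for 240 without the arrays that stand apart (90 weaker, 3 moved, 1 stronger). They held for 2903 of 3296 values with 1 array left out (356 weaker, 33 moved, 4 stronger) and for 158 of 423 values from other probe sets (179 weaker, 85 moved, 1 reversed). Weaker values kept the sign but lost the call, and moved values had the opposite sign without passing. So 85 of the 423 values from other probe sets pointed the other way without passing, and 1 did so past the threshold. This reversed value was ZNF236 in vehicle A549, 24 h minus 6 h, at -1.46, and 0.63 by its other probe set. The cause was not tested. In A549 at 6 h, 63 of 100 named genes past the threshold lost the call and 5 changed sign with quantile normalization (FN1, ALDH3A1, UCHL1, TUBB4B and RPL14).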

Other observations

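All values in this part were looked at after the results were seen. Of the genes higher with GSI in H460a at 6 h, 9 of 14 were also higher in A549 at 6 h, where 1.63 would be shared by independent draws: ALG2, CCNG2, DNAJB9, DNAJC3, GDF15, HERPUD1, INSIG1, SLC33A1 and VASN. These comparisons share no arrays, but the variance of each gene comes from 1 fit over all 32 arrays. A gene with a small spread is thus more readily called in both, so independent draws are not a fair reference. The same holds for the other overlaps below. The 2301 higher genes in A549 at 6 h fall to 265 with quantile normalization over all arrays, and then 7 of 15 were shared (0.201 by independent draws): DNAJB9, HERPUD1, HSPA13, INSIG1, MIS12, SLC33A1 and VASN. GDF15 loses its call in both lines there. Of the lower genes, 1 of 5, PSAPL1, was shared. In A549, 68 genes were higher at both 6 and 24 h (30.5 by independent draws) and 26 lower at both (2.65), against 30 (4.46) and 42 (4.10) with quantile normalization. HES1, HEY1, HES4, JUNB, PMEPA1, ANGPTL4, JAG2 and LBH were lower at both times either way.

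Across the 19775 genes, which are not independent replicates, the Pearson correlation of the GSI effects was 0.208 between A549 and H460a at 6 h and 0.0546 at 24 h. Between 6 and 24 h it was 0.0113 in A549 and 0.0623 in H460a. Over the 437 genes past the threshold in A549 at 24 h it was 0.478 between 6 and 24 h in A549, with 69.6% of the same sign, and 0.255 between the lines at 24 h, with 60.4%. The first 3 principal components of the arrays held 81.9%, 5.99% and 4.63% of the variance. The 4 poly-A controls lay between 3.78 and 5.16 on the log2 scale, near the low end of the arrays, and the hybridization control cre between 13.8 and 14.7.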
